A study of Mus musculus with 6 samples.

How the data were processed

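Neural stem cells and neural progenitors of adult mice were profiled on 1-colour Affymetrix whole-transcript arrays, 1 array per sample. The labels name 2 genotypes of the 129SV strain. Control mice carried floxed Sirt1 alleles without Cre, and the other mice carried the same alleles together with a Cre recombinase under the Nestin promoter, which acts in neural stem and progenitor cells; the labels describe these cells as lacking active SIRT1. Each genotype has 3 samples, which the sample titles call biological replicates. How many mice each sample came from is not given in the sources used here. Cells were taken from mice of 8 weeks, expanded as neurospheres with EGF and bFGF, replated as attached cells and collected while proliferating, at passage 2.

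The values deposited by the authors are log2 expression values, 1 per probe set and array, made with RMA per the submitters' processing notes and the series' design text. RMA subtracts background, gives all arrays nearly one distribution of intensities and summarises the probes of a probe set. The log2 scale was read from the deposited values themselves, which ranged from 3.02 to 13.6 with array medians between 7.36 and 7.39. The version of RMA and the genome build behind the array's annotation are not given in the sources used here, so no coordinates are printed. RMA forces array-wide differences in brightness to nearly vanish and compresses the differences of dim probe sets, so a fold change is on the RMA scale and can understate the change in RNA. The table held 0 columns of other samples.

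The table has 34760 probe sets. GEO's platform annotation pairs 21640 of them with 1 gene, 1321 with several genes and 11799 with none in the table used. The 22961 probe sets with at least 1 gene were tested. Genes are named only from probe sets with 1 gene. Gene symbols were looked up by Entrez identifier in NCBI RefSeq's gene table for assembly GRCm38.p6, which held 21553 of the single-gene probe sets and changed 0 symbols. No further normalization was applied to the deposited values. Arrays have no read depth, and the number of arrays limits the precision: the median standard error of a log2 difference was 0.080, and the median 95% interval reached 0.19 to either side.

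Differences are Sirt1 inactive minus control. They were fitted over all 6 arrays with limma 3.58.1 in R 4.3.3, by a linear model per probe set with genotype as the term, followed by empirical Bayes moderation. The p-values are two-sided and Benjamini-Hochberg adjusted over the tested probe sets, with a threshold of 0.05. Adjusted p-values in the text come from limma unless another test is named. An exact two-sided permutation test of 3 against 3 values cannot give a p below 0.1. Values are given as mean ± SD over 3 arrays, and standard errors (SE) are limma's.

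Before the data were examined, 30 gene lists were fixed, with 584 entries, of which 547 were measured by a single-gene probe set. They cover markers of oligodendrocyte progenitors, myelinating oligodendrocytes, astrocytes, neural stem cells, neuroblasts and neurons, microglia and macrophages, endothelium, mural cells and fibroblasts, and ependyma. They also cover G1/S and DNA replication, G2/M and mitosis, growth factor and mTOR signalling, MAPK output, glycolysis, oxidative phosphorylation, fatty acid oxidation, fatty acid and cholesterol synthesis, the Notch pathway, p53, FOXO, NF-kB, interferon, Wnt, BMP, NRF2 and hypoxia targets, the unfolded protein response, other sirtuins and NAD metabolism, the circadian clock and cytosolic ribosomal proteins. Some genes stand in more than 1 list. Each list was tested against all 19938 measured genes, 1 probe set per gene (the one with the highest mean), with limma's camera at a preset correlation of 0.01 between genes, and adjusted over the 30 lists. Camera with an estimated correlation and fry, a rotation test of each list by itself, were alternatives. A list's value is the mean log2 difference of its measured members.

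The rule for named genes was also fixed before the data were examined. Sirt1 comes first. Then come the 12 genes per direction past the threshold with the largest change and no overlap between the groups, with places left open filled by the smallest unadjusted p; for each list, up to 4 members with the smallest unadjusted p follow. Predicted genes without a name were not named. Because no gene passed over all probe sets, all 12 places per direction hold genes that did not pass. Genes named outside this rule are said to be chosen after their values were seen. The Y-linked genes Uty, Kdm5d and Eif2s3y and the X-inactivation transcript Xist were read as a check of the sex of the mice; Ddx3y was not analysed here.

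The fit was tested on simulated data for the comparison of Sirt1 inactive with control, with 22961 probe sets, 200 of them changed, in 20 simulations. It recovered 66.5% of changes of 0.5 on the log2 scale, 96.1% of changes of 1 and 99.7% of changes of 2, with a mean of 11.35 false calls. A shift of 0.3 given to the oligodendrocyte progenitor list was called in 20 of 20 simulations with the preset correlation and in 19 with the estimated one, with 0 calls of other lists. The simulated genes vary independently of each other, which real genes of a list do not. Values were drawn from a normal distribution with each probe set's moderated SD, with no array apart from the others and no pairs. The shares recovered therefore need not hold for the real arrays.

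The labels number the samples 1 to 3 in each genotype without saying what a number shares. Deviations from the genotype means correlated between the arrays of number 1 (0.47), number 2 (0.36) and number 3 (0.27), while every other pairing across genotypes was below 0. Because deviations sum to 0 within a genotype, positive values for same numbers push the others below 0, which adds no evidence. The correlations were seen in the same output as the calls of the fit with the replicate number as a block. They are across probe sets, with only 3 arrays per genotype behind them, so they do not establish what a number shares. Each same-number correlation exceeds the 0.1 set for treating the numbers as pairs. The numbers were therefore taken to pair the samples, and the fit with the replicate number as a block is given beside a result wherever it changes a call or moves a count by over 1.5 times. No arrays were near copies of each other. The most alike, control replicate 2 and Sirt1 inactive replicate 3, carry different numbers and differed by a median of 0.073. Same-numbered arrays differed by 0.074 (number 1), 0.082 (number 2) and 0.123 (number 3). Likeness of the arrays alone therefore does not give these pairs.

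Alternatives were the replicate block, each array left out in turn, filters on dim probe sets, all probe sets of the table, 1 probe set per gene, an intensity trend with robust prior, array weights, a renewed quantile normalization, subtraction of array medians, other thresholds, leaving out the sex-linked genes, and other list tests. The count at an unadjusted p over all 6 arrays was planned. Leaving out both arrays of number 3, counts at an unadjusted p under the other alternatives and the count of entries adjusted over a list alone under the alternatives were added after seeing the data.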

Results

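Expression was measured in 6 cultures of proliferating neural stem cells and progenitors from adult mice, 3 with floxed Sirt1 alleles only (control) and 3 that also carried Nestin-Cre (Sirt1 inactive). Each array gave a log2 RMA value for 34760 probe sets, with array medians of 7.36 to 7.39. Every array had Uty between 8.68 and 8.89 and Xist between 5.15 and 5.40, so all 6 cultures carried Y-linked expression. The comparison of the genotypes asks how the transcripts of these cells differ when SIRT1, an NAD-dependent deacetylase, is not active. The controls carry no Cre, so an effect of Cre itself is part of the difference. Control replicate 3 lay apart from the other 5 arrays, with a median absolute distance of 0.117 to their mean against 0.089 for the next most distant array, Sirt1 inactive replicate 2.

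Sirt1 itself (probe set 10369738) was lower in the Sirt1 inactive cultures, at 8.28 ± 0.04 (SD, n = 3) against 8.68 ± 0.12 (SD, n = 3) in control. The control arrays read 8.73, 8.78 and 8.55 and the Sirt1 inactive arrays 8.26, 8.33 and 8.25. The log2 difference was -0.41 (SE 0.08, 95% interval -0.58 to -0.23), a level of 0.755 times control, lower in 3 of 3 same-numbered pairs. It did not pass the test over all probe sets (limma, adjusted p = 0.959; unadjusted p = 0.00101), and the exact permutation test gave the smallest p that 3 against 3 allows, 0.1. The probe set covers the whole transcript, and which part of the gene is floxed is not given in the sources used here, so this value need not report a partial deletion.

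Gpr17, a receptor of committed oligodendrocyte precursors, and C1ql1, a secreted C1q-like protein made by the same lineage, had the smallest p among the genes with higher values without active SIRT1. Gpr17 was 8.41 ± 0.34 against 7.66 ± 0.14 in control (SD, n = 3), a difference of 0.75 (SE 0.17), or 1.68-fold. C1ql1 was 8.78 ± 0.16 against 8.34 ± 0.11 (SD, n = 3), a difference of 0.44 (SE 0.10). Next in order were Lims2, an adaptor of focal adhesions (0.25), Tfb2m, a mitochondrial transcription factor (0.35), Dennd4a (0.24), Gmnc, a regulator of multiciliated cells (0.40), Wars2, the mitochondrial tryptophanyl-tRNA synthetase (0.28), Myo9a (0.30), Tdgf1 (0.28), Rpl13 (0.54), Clca3a2 (0.27) and Stk26 (0.35). Among genes with lower values, Klk1b11, a kallikrein, differed by -0.37, Nnat, an imprinted gene of the developing brain, by -0.34, and Fgf14, which binds voltage-gated sodium channels, by -0.49. Lsm5 differed by -0.32, Tmem178b by -0.62, Zcchc12 by -0.48, Apoc4 by -0.30, the miR-124 gene Mir124a-2 by -0.25, the galactosyltransferase gene B3galt5 by -0.62, the Wnt modulator Sfrp4 by -0.34 and Nudt11 by -0.49. All of these genes had groups that did not overlap and the same direction in 3 of 3 pairs, which is what they were chosen for. Rpl13, Klk1b11, Clca3a2 and Tdgf1 have near-identical relatives or pseudogenes, so their probes can read other transcripts. Some of these genes were dim in at least 1 genotype, near or below the lower quartile of the arrays (5.78 to 5.83). They were Klk1b11 (5.48 against 5.85 in control), Clca3a2 (5.39 against 5.12), Gmnc (6.24 against 5.84) and Stk26 (6.11 against 5.77). Whether such values lie above background cannot be read from RMA values.

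None of these genes passed over all probe sets (limma, adjusted p = 0.959). In all, 0 of 22961 probe sets passed, also with the replicate number as a block, where the smallest adjusted p was 0.51. At an unadjusted p under 0.05 there were 830 probe sets, 226 higher and 604 lower, against 1148 given by chance, and 1741 with the block. The share of these that were higher was 27.2%, but 50.7% when array medians were subtracted, 34.6% after a renewed quantile normalization and 41.7% without the probe sets below the median brightness. Over all tested probe sets 60.1% had a difference below 0, which is the share to set beside counts of list members below 0. The groups did not overlap for 9.33% of probe sets, where chance gives 10%. The count of 830 was 1453 without control replicate 1 and 456 without Sirt1 inactive replicate 2.

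**Figure D1:**
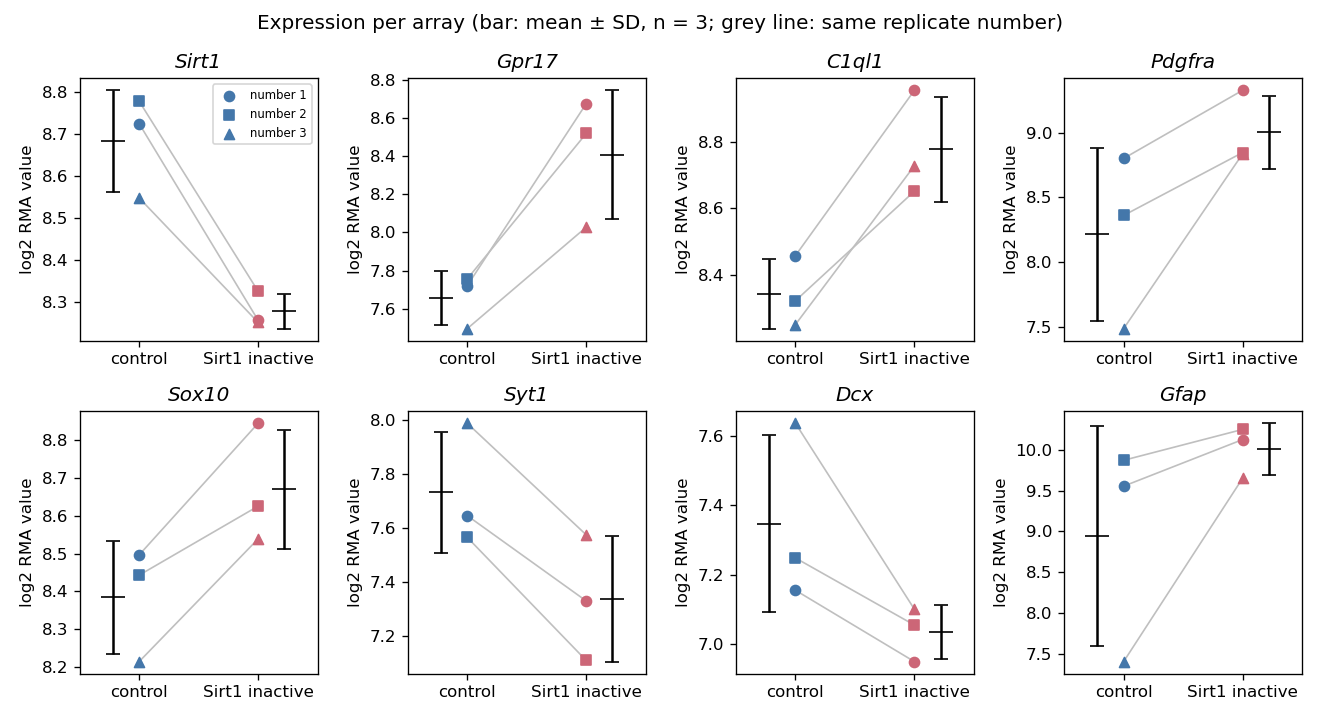
Log2 RMA values of 8 genes per array, with control on the left and Sirt1 inactive on the right of each panel; marker shapes give the replicate number, grey lines join arrays of one number, and bars are mean ± SD over 3 arrays. Gpr17 and C1ql1 lie above all controls in all 3 Sirt1 inactive cultures, Sirt1 lies below, and Gfap is set apart mainly by the 7.41 of control replicate 3.

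Of the 19 measured oligodendrocyte progenitor markers, Gpr17 and C1ql1 passed when adjusted over the list alone (adjusted p = 0.026 for both), and 0 passed over all probe sets. Sox10, a transcription factor of the lineage (8.67 ± 0.16 against 8.38 ± 0.15), and Pdgfra, its PDGF receptor (9.003 ± 0.281 against 8.22 ± 0.67), differed by 0.28 and 0.79 and did not pass (SD, n = 3; limma, adjusted p = 0.18 over the list alone). With the replicate block all 4 passed over the list alone, at adjusted p = 0.0057 for Gpr17, 0.0062 for C1ql1 and 0.028 for Sox10 and Pdgfra. The list as a whole did not pass: 6 members were above 0 and 13 below, its mean difference was 0.01 and its median -0.10, and the camera test, whose direction was higher, gave an adjusted p = 0.67 (0.82 with an estimated correlation). Olig2, named here after its values were seen, was -0.15 (SE 0.10). No member passed without control replicate 2, control replicate 3, Sirt1 inactive replicate 1 or Sirt1 inactive replicate 2, where the difference of Gpr17 was 0.80, 0.67, 0.62 and 0.70, with adjusted p = 0.093, 0.065, 0.084 and 0.12. With array weights C1ql1 passed (0.43, adjusted p = 0.019) and Gpr17 did not (0.59, 0.082). Without Sirt1 inactive replicate 3 Gpr17 alone passed, and without control replicate 1 Pdgfra passed too. Pdgfra was 7.49 in control replicate 3, and its difference without that array was 0.42. With both arrays of number 3 left out and the block kept, a fit added after the data were seen, 5 members passed over the list alone: Gpr17 (0.86, adjusted p = 0.00035), C1ql1 (0.42, 0.0070), Sox10 (0.27, 0.040) and Pdgfra (0.51, 0.0019) were higher and Vcan was lower (-0.35, 0.030). With all 6 arrays Vcan differed by -0.26 and did not pass (adjusted p = 0.18 over the list alone). Of 24 myelinating oligodendrocyte markers 19 were below 0, with Gjb1 at -0.16, Mbp at -0.16 and Mal at -0.17 and Nfasc at 0.20; their mean was -0.07 and the list did not pass (adjusted p = 0.15), although it did without control replicate 3 (adjusted p = 0.0044) and without Sirt1 inactive replicate 1 (0.019), with array weights (0.032) and in the paired fit without number 3 (0.023).

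Neuroblast and neuron markers were lower on balance: 18 of 25 were below 0, with a mean difference of -0.15. Syt1, a calcium sensor of synaptic vesicles, was 7.34 ± 0.23 against 7.73 ± 0.22 (SD, n = 3), a difference of -0.39. Gap43, a growth cone protein, differed by -0.31, Dcx, a microtubule protein of migrating neuroblasts, by -0.31, and Snap25, of the synaptic fusion machinery, by -0.51. None passed over the list alone, while with the replicate block 3 members fell, Syt1 (limma, adjusted p = 0.021 over the list alone), Gap43 (0.041) and Elavl4 (-0.44, 0.041), the last named after its values were seen. Without control replicate 3, in the fit with no block, Elavl4 was -0.08 (adjusted p = 0.84 over the list alone), and in the paired fit without number 3 it was -0.32 (0.021), while Gap43 did not pass there (adjusted p = 0.0504). The list passed the camera test (adjusted p = 0.042, and 0.0045 with the block), but not with an estimated correlation (adjusted p = 0.61). The camera call held in the paired fit without number 3 (mean -0.12, adjusted p = 0.020) and with array weights (mean -0.12, adjusted p = 0.011). Without control replicate 3 and with no block, the mean was -0.08 and the call was lost (adjusted p = 0.12). The call was also lost, with means of -0.12 to -0.15, after a renewed quantile normalization (adjusted p = 0.065) and without control replicate 2 (0.27), Sirt1 inactive replicate 1 (0.14) or Sirt1 inactive replicate 2 (0.11). Control replicate 3 had the highest mean of the list, 0.20 above the mean of the arrays.

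Astrocyte markers were higher on balance, with 16 of 20 above 0 and a mean difference of 0.18. The glial filament gene Gfap was 10.01 ± 0.32 against 8.94 ± 1.34 (SD, n = 3), a difference of 1.06 (SE 0.60) that was 0.29 without control replicate 3 and 0.47 in the paired fit without number 3, where it passed over its list (adjusted p = 0.013). Atp1b2, a sodium pump subunit, differed by 0.19 and Aldoc, an aldolase of astrocytes, by 0.27, while Sox9, a transcription factor of glia and stem cells, differed by -0.25. No member passed over the list alone. The list passed the camera test (adjusted p = 0.00071), but not with an estimated correlation (adjusted p = 0.61) and not without control replicate 3, where its mean difference was 0.005 (adjusted p = 0.47). It was lost with array weights too (mean 0.06, adjusted p = 0.053). Control replicate 3 lay 0.44 below the mean of the arrays for this list. Neural stem cell markers had a mean difference of 0.05 and did not pass (adjusted p = 0.11); Nr2e1 was 0.18, Hopx -0.15, Hes1 0.15 and Vcam1 0.51, and the list passed without control replicate 2 (adjusted p = 0.031) and without Sirt1 inactive replicate 3 (0.0495).

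Markers of cell types that such cultures can hold in small numbers gave no call. Microglia and macrophage markers had a mean difference of -0.07 (adjusted p = 0.076), or -0.04 with array medians subtracted. Of these markers 15 of 17 were below 0, against 60.1% of all tested probe sets. Tmem119 differed by -0.19, Itgam by -0.16, Trem2 by -0.14 and P2ry12 by -0.17. This list passed without control replicate 1 (adjusted p = 0.045) and without control replicate 3 (0.030), and with array weights (mean -0.12, adjusted p = 0.0050). Mural cell and fibroblast markers had a mean of 0.11 (adjusted p = 0.17), with Dcn at 0.55, Postn at 0.49, a direction that turned without control replicate 3, Lum at -0.25 and Col1a1 at -0.15; control replicate 3 lay 0.41 below the mean of the arrays, and the list passed without control replicate 2 (adjusted p = 0.010). Ependymal markers had a mean of -0.06 (adjusted p = 0.21), with Tekt1 at -0.12, Mia at -0.11, Dynlrb2 at -0.09 and Ak7 at -0.07. Endothelial markers had a mean of -0.004 (adjusted p = 0.94), a sign that turned under both other scalings, with Slco1a4 at 0.23, Cdh5 at -0.15, Tek at -0.13 and Tie1 at -0.08.

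Genes of energy metabolism were higher on balance, by small amounts. For oxidative phosphorylation 24 of 27 members were above 0, with a mean difference of 0.06, and Cycs, cytochrome c, differed by 0.22, Sdha by 0.13, Cyc1 by 0.12 and Ndufb5 by 0.10. For fatty acid oxidation and PPAR targets 14 of 16 were above 0, with a mean of 0.11; Cpt2, of mitochondrial fatty acid import, differed by 0.24, Acadl by 0.25, Acadm by 0.19 and Acadvl by 0.15. All 15 measured glycolysis genes were above 0, with a mean of 0.09, among them Pfkp (0.25), Slc2a1 (0.17), Pfkl (0.13) and Hk1 (0.08). Fatty acid and cholesterol synthesis had a mean of 0.03, with Sc5d at 0.15, Idi1 at 0.12, Lss at 0.10 and Insig1 at 0.08. No member of these 4 lists passed over its list alone. The lists passed the camera test (adjusted p = 1.7e-06 for oxidative phosphorylation, 0.00014 for fatty acid oxidation, 0.00065 for glycolysis and 0.028 for fatty acid and cholesterol synthesis), and none did with an estimated correlation (adjusted p = 0.61 for each). In the paired fit without number 3 oxidative phosphorylation (mean 0.03, adjusted p = 0.055), fatty acid oxidation (mean 0.03, 0.14) and lipid synthesis (mean 0.02, 0.14) did not pass. Without control replicate 3, which lay 0.23 below the mean of the arrays for fatty acid oxidation, that list no longer passed (mean 0.02, adjusted p = 0.34). Without Sirt1 inactive replicate 2, which lay 0.16 above the mean for glycolysis, neither glycolysis (mean 0.03, adjusted p = 0.085) nor lipid synthesis (0.094) passed, and lipid synthesis also did not without control replicate 1 (0.30) or Sirt1 inactive replicate 3 (0.25), or after a renewed quantile normalization (0.076).

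NF-kB and inflammatory targets (mean 0.13, adjusted p = 0.048), NRF2 antioxidant targets (mean 0.08, adjusted p = 0.014) and hypoxia targets (mean 0.08, adjusted p = 0.0051) passed the camera test in the direction higher. With an estimated correlation none passed (adjusted p = 0.61 for each), and no member passed over its list alone. In the paired fit without number 3 Cxcl10, Ptgs2, Slc7a11 and Ndrg1 passed the two-sided test over their lists alone. Their directions in that fit are not given here, so these passes are not read as rises. The list means there were -0.014 for NF-kB targets, 0.008 for NRF2 targets and 0.11 for hypoxia targets. Ptgs2 and Ndrg1 are named here after their values were seen. Among NF-kB targets Cxcl10 differed by 0.59 and Nfkbiz by 0.27, while Il1b differed by -0.17 and Ccl5 by -0.12; control replicate 3 lay 0.39 below the mean of the arrays, and without it the list mean was -0.03 (adjusted p = 0.47). The NF-kB call was also lost without Sirt1 inactive replicate 1 (adjusted p = 0.13) or 2 (0.14), with array weights (0.74), with array medians subtracted (0.087) and with an intensity trend and robust prior (0.0502). Among NRF2 targets Slc7a11 was at 0.27, Prdx1 at 0.19, Me1 at 0.15 and Gclm at 0.13; without control replicate 3, 0.17 below the mean of the arrays, the list mean was 0.01 (adjusted p = 0.34), and without Sirt1 inactive replicate 1 (0.13) or in the paired fit without number 3 (0.52) it did not pass either. Among hypoxia targets Egln3 was at 0.20, Higd1a at 0.18, Slc2a1 at 0.17 and Car9 at 0.17. Sirt1 inactive replicate 2 lay 0.23 above the mean of the arrays for hypoxia targets, and without it the list mean was -0.02 (adjusted p = 0.86); with array weights the mean was 0.02 (adjusted p = 0.32).

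**Figure D2:**
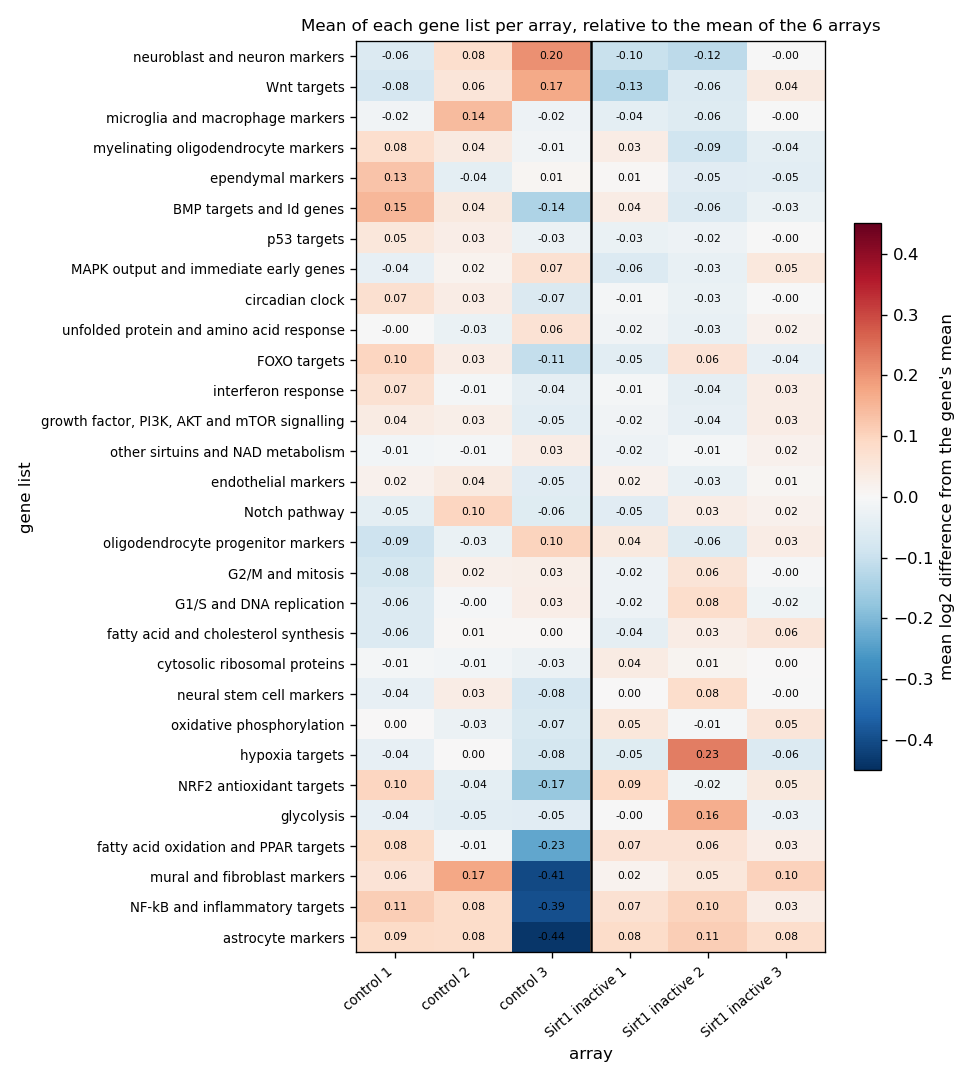
Mean of each of the 30 gene lists per array, as the mean log2 difference of its genes from their own mean over the 6 arrays, with controls left of the line and Sirt1 inactive right of it. Control replicate 3 is the lowest array for astrocyte markers (-0.44), mural and fibroblast markers (-0.41) and NF-kB targets (-0.39), and Sirt1 inactive replicate 2 the highest for hypoxia targets (0.23) and glycolysis (0.16).

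Cell cycle genes differed little. G1/S and DNA replication genes had a mean difference of 0.02, with 15 of 23 above 0; Rrm2 was at 0.14, Ccne2 at 0.11, Mcm3 at 0.10 and Ccne1 at 0.09. This list passed the camera test in the direction higher (adjusted p = 0.030), but not with an estimated correlation (adjusted p = 0.62), after a renewed quantile normalization (0.065) or with array weights (0.27), and its mean turned below 0 without control replicate 1 (-0.0009, adjusted p = 0.41) or Sirt1 inactive replicate 2 (-0.009, adjusted p = 0.60). G2/M and mitosis genes had a mean of 0.02 and did not pass (adjusted p = 0.061), with Hmmr at 0.16, Kif11 at 0.10, Prc1 at 0.08 and Aurkb at -0.08; they passed when control replicate 2, control replicate 3, Sirt1 inactive replicate 1 or Sirt1 inactive replicate 3 was left out (adjusted p = 0.015, 0.022, 0.035 and 0.049), with array medians subtracted (0.036), with camera on ranks (0.049), with the mean of a gene's probe sets (0.043) and in the paired fit without number 3 (0.023). Their mean turned below 0 without control replicate 1 (-0.014, adjusted p = 0.81) or Sirt1 inactive replicate 2 (-0.004, 0.46). Cytosolic ribosomal protein genes had a mean of 0.03 (adjusted p = 0.089), with Rpl14 at 0.26, Rpl5 at 0.23, Rps6 at 0.09 and Rpl7 at 0.08, the last with a direction that turned without Sirt1 inactive replicate 1.

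The other signalling and stress lists did not pass. Wnt targets had a mean difference of -0.10 (adjusted p = 0.15), with Nkd1 at -0.37, Notum at -0.14, Tnfrsf19 at -0.11 and Sp5 at -0.09. BMP targets and Id genes had a mean of -0.04 (adjusted p = 0.82), with Smad6 at -0.14, Msx1 at -0.23, Msx2 at -0.12 and Bmp4 at 0.19, whose direction turned without control replicate 3, and circadian clock genes of -0.03 (adjusted p = 0.84), with Hlf at -0.22, Per1 at -0.13, Nr1d1 at -0.08 and Bhlhe41 at 0.16. Without control replicate 3 both lists passed in the direction lower (adjusted p = 0.0083 and 0.040), and in the paired fit without number 3 BMP targets did too (mean -0.11, adjusted p = 0.012). p53 targets had a mean of -0.04 (adjusted p = 0.74), with Plk2 at -0.34, Sesn2 at -0.22, Sesn1 at -0.16 and Trp53inp1 at -0.14, and MAPK output of -0.03 (adjusted p = 0.76), with Etv5 at -0.15, Spred2 at -0.11, Etv1 at -0.10 and Ier3 at 0.22. The Notch pathway had a mean of 0.003 (adjusted p = 0.24), with Notch3 at 0.21, Hes1 at 0.15, Jag2 at -0.16 and Dtx1 at -0.21, and passed without control replicate 2 (adjusted p = 0.015).

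Means closer to 0 changed sign when array medians were subtracted for growth factor, PI3K, AKT and mTOR signalling (-0.01, adjusted p = 0.94), FOXO targets (-0.02, adjusted p = 0.94), the interferon response (-0.01, adjusted p = 0.76), the unfolded protein and amino acid response (-0.02, adjusted p = 0.49) and other sirtuins and NAD metabolism (-0.008, adjusted p = 0.74). Among their members Pik3r1 was at -0.11, Irs1 at -0.12, Igf1r at -0.11 and Gsk3b at -0.05, and Cat at -0.17, Ccng2 at -0.16 and Sesn3 at -0.08. Rsad2 was at -0.34, Mx1 at 0.15, Usp18 at -0.13 and Bst2 at 0.07 (turned without control replicate 2), while Ddit3 was at -0.17, Herpud1 at -0.15, Atf4 at -0.12 and Creld2 at 0.12. Of NAD enzymes, Nmrk1 was at 0.32, Nmnat1 at 0.13, Qprt at -0.21 and Bst1 at -0.10. The camera direction, which is relative to all other genes with their median difference of -0.02, was higher although the mean was below 0 for growth factor signalling, the interferon response, the unfolded protein response and the sirtuin list. The median was above 0 for the unfolded protein response (0.02) and the sirtuin list (0.02).

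Over all lists, 9 of 30 passed the camera test higher and 1 lower at the preset correlation, with the same numbers under the replicate block. With an estimated correlation 0 passed, and fry called 0 (smallest adjusted p = 0.73). Adjusted over each list alone, 2 of the 547 entries passed, or 7 with the replicate block.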

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

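Counts at an unadjusted p under alternatives, counts adjusted over a list alone under alternatives and the fit without the arrays of number 3 were chosen after the data were seen; the other alternatives, and the unadjusted threshold over all arrays, were planned before. No probe set passed under any alternative with all 6 arrays or with 1 array left out (0 to 0 probe sets in either direction), at an adjusted p under 0.1, or at a minimum size of 0.5. With the replicate block and both arrays of number 3 left out, 19 probe sets passed, 5 higher and 14 lower, on 4 arrays. At an unadjusted p the threshold gave 830, 226 higher and 604 lower. That count was 1741 with the replicate block, 312 without the probe sets below the median brightness, 1376 over all probe sets of the table, 1972 with the block and number 3 left out, and 456 to 1453 with 1 array left out. The filter and the full table change how many probe sets are tested; for the others the cause was not tested. Sirt1 stayed lower, from -0.47 to -0.36, with adjusted p from 0.11 to 1.00. The 24 named genes kept their direction in all 387 values, and 1 value passed, Gpr17 with the block and number 3 left out (adjusted p = 0.033). These genes were chosen for groups that do not overlap. Only the renewed quantile normalization and the subtraction of array medians could therefore have turned a direction. List members were followed for 121 entries only, those with the smallest p in their list or a pass under the replicate block. Of their 2017 values, 8 had another direction, none of them past the threshold: Postn and Bmp4 in 2 settings each and Bst2, Rpl7, Nfasc and Bhlhe41 in 1 each. Members chosen for a small p say little about the direction of the other entries.

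Adjusted over the list alone, 2 entries became 7 with the replicate block, 1 with array weights, 18 with the block and number 3 left out, and 0 to 4 with 1 array left out. The 18 included Dcn, Rgs5, Lyz2, Hey2, Msx1 and Stmn2, which were not named as passing in the paragraphs on their lists. Lists called higher, 9 at first, were 5 with array weights, 0 with an estimated correlation, 0 by fry, 4 with the block and number 3 left out, and 4 to 13 with 1 array left out. Lists called lower, 1 at first, were 3 with array weights, 0 after a renewed quantile normalization, 0 with an estimated correlation, 0 by fry, 3 with the block and number 3 left out, and 0 to 4 with 1 array left out. The replicate block changed no list's call. Means turned below 0 for 3 called lists. With 1 array left out G1/S and DNA replication ranged from -0.0088 to 0.045, NF-kB targets from -0.031 to 0.22 and hypoxia targets from -0.020 to 0.13, and NF-kB targets were -0.014 with the block and number 3 left out. The cause was not tested. Of 318 values of lists that passed in neither setting, 36 had another direction. Signal over background cannot be read from RMA values, so the effect of dimness was followed only through the brightness filters on probe sets. The list tests were not repeated under these filters. The median log2 difference was -0.022 over all tested probe sets and -0.003 without those below the median brightness. Whether brightness moved a list's call was not tested.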

Other observations

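Of the tests in this part, those of an array-wide shift, of dim probe sets and of the splits for counts within a list were set down before their results were seen, and all others after. The genes of this part were chosen after their values were seen. Control replicate 3 had 156 genes at least 1 lower and 56 at least 1 higher on the log2 scale than the mean of the other 5 arrays, against 3 and 51 for control replicate 1 and at most 8 for the others. The genes low in it included Gfap (7.41 against 9.89), the astrocyte water channel gene Aqp4 (8.42 against 10.3), Lcn2, a secreted protein of reactive glia (10.4 against 12.5), Ttr, a product of the choroid plexus (9.08 against 11.1), Sulf1 (7.33 against 9.78) and Otx2 (7.14 against 8.99). Those high in it included the GABA receptor genes Gabbr2 (10.4 against 8.48) and Gabra2 (10.6 against 9.32), and Gng3 (10.2 against 8.59), Tagln3 (10.7 against 9.08) and Thy1 (11.1 against 9.81), all genes expressed in neurons. Gfap (1.06), Ttr (1.02) and Gng3 (-1.08) are also the single-gene probe sets with a genotype difference of at least 1, and did not pass (adjusted p = 0.959, limma).

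When both arrays of number 3 were left out and the replicate number was a block, 19 probe sets passed over all probe sets, 15 of them with 1 gene. The lower genes were Zim1 (-1.11), Ecm2 (-1.10), Calb2 (-1.08), the Y-linked Srsy (-1.08), the glutamate receptor gene Gria1 (-0.87), Pcp4l1 (-0.83), Stmn2, a neuronal microtubule protein (-0.78), Asb4 (-0.74), Peg3 (-0.71), Hs3st2 (-0.71), Ccbe1 (-0.70) and Lipg (-0.67). The higher genes were the ribosomal protein genes Rpl36 (0.94) and Rps13 (0.85), which have many pseudogenes, and Gpr17 (0.86). With all 6 arrays and no block none of these passed, for example at -0.67 for Calb2, -0.26 for Stmn2, -0.51 for Gria1, -0.57 for Peg3, -0.69 for Zim1 and -0.44 for Asb4. The calls rest on 4 arrays in 2 pairs. The other way of crossing these pairs gave 0 probe sets, with 571 at an unadjusted p under 0.05 against 1972; 2 splits are too few to exclude chance.

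The departure of control replicate 3 was not removed by putting all arrays on one distribution. Its distance from the other arrays was 1.311 times that of the next most distant array as deposited. After that step it was 1.215 times (95% interval 1.184 to 1.239). RMA had already given the arrays nearly one distribution, so this argues only against a remaining array-wide shift in intensity as the whole cause. Over the brightest 25% of probe sets the ratio was 1.213 (1.167 to 1.257), which argues against noise of dim probe sets as the whole cause. Both intervals resample probe sets of the same arrays, so they do not measure variation between cultures. A smaller share of astrocyte-like cells in that culture may be part of it, since 14 of 20 astrocyte markers were lowest in that array; this cannot be told apart from a lower expression of these genes per cell, and Acsbg1 (11.8 in that array) was within the range of the other arrays. The labels give that culture no property of its own to test.

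The 10 list calls at the preset correlation are open to the way genes of a list vary together. The correlation estimated for the called lists had a median of 0.2286, far above the preset 0.01, and with the estimated values 0 lists passed, which is consistent with calls made by variation between cultures. As many lists were called in 4 of the 10 splits of the 6 arrays, the real one included, with 10 for the real split and 10 for the highest other. Of the 4 splits that part all pairs, with the replicate block, 3 called as many lists (10 for the real split, 10 for the highest other) and 1, the real one, gave as many probe sets at an unadjusted p (1741, against 1065 for the highest other). With no block 5 of the 10 splits gave as many probe sets, with 830 for the real split and 2334 for the highest other, which set control replicates 1 and 3 and Sirt1 inactive replicate 1 against the rest and points to a structure of the samples that genotype does not give; neither 10 nor 4 splits can give a share under 0.05.

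Higher Gpr17, C1ql1, Sox10 and Pdgfra with lower neuronal genes may be a hypothesis worth following, namely more progenitors committed to the oligodendrocyte lineage without active SIRT1. A loss of neuron-like cells as the whole cause would raise the markers of all other cells alike. The score of the neural stem cell markers (the median over genes of the departure from their mean, per array) differed between genotypes by 0.05. Its 95% t interval over 3 and 3 arrays, which does not use the pairing, was -0.03 to 0.13. The 4 genes exceeded that score by 0.4555 (-0.006 to 0.917, also unpaired). That interval reaches 0 for genes chosen for their values, and no paired interval was computed. A loss of neuron-like cells therefore stays open. Whether control replicate 3 is the whole cause is not settled. In the paired fit without number 3 all 4 genes passed with adjustment over all 19 members of the list, and Vcan passed as lower. The median of the 4 there was 0.4612 (SE 0.088 over 2 pairs). The 4 genes were picked from a fit that held these same pairs, so passing again cannot exclude that array as the whole cause. With that array left out and no pairing none passed, and the median was 0.41 (SE 0.18). Counted over lists alone, 5 of 10 splits gave as many entries (2 for the real split, 9 for the highest other), and with the replicate block 1 of the 4 splits that part all pairs did, the real one (7, against 5 for the highest other); both sets of splits are too few for a share under 0.05. The progenitor list as a whole did not rise with the 4 genes. In control replicate 3 it went the other way. That array had the highest mean of the list, 0.10 above the mean of the arrays, and the lowest value of each of the 4 genes. The score of all 19 progenitor markers differed by -0.05 (unpaired 95% interval -0.22 to 0.11), and the 4 genes exceeded it by 0.56 (-0.03 to 1.15). Of the 19 progenitor markers 13 were below 0, Olig2 among them, as were 19 of 24 myelinating oligodendrocyte markers, against 60.1% of all tested probe sets. Cell counts would be needed to separate more cells from more transcript per cell.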
